A study of Caenorhabditis elegans with 33 samples.

How the data were processed

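33 libraries were analysed: 8 small RNA libraries of unfed worms, 14 siRNA libraries of worms fed sel-1 double-stranded RNA or the empty vector L4440, and 11 3′ RACE libraries of sel-1. Small RNAs were untreated (direct) or treated with phosphatase and then polynucleotide kinase (CIPPNK), per the labels' protocols. Reads were aligned with Bowtie 0.12.9, per the submitters' processing notes. How reads were trimmed and filtered is not stated.

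For the unfed worms, the authors deposited expected counts: each sequence's reads divided by its number of matching positions, with 1 line per position, rounded and not scaled to depth, as read from the values. Because of that rounding, values of sequences with many positions are listed as 0 (from 18.2% to 41.2% of lines). For sel-1 siRNAs and 3′ RACE, the authors deposited counts of reads per distinct sequence, whole numbers in the files, with no library depth. The 3′ RACE files split each read into a part that matches sel-1 and an unmatched rest, and list only reads with such a rest. Between 0.191% and 0.243% of lines in the time course 3′ RACE files had an extra field and were left out.

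Features were matched by sequence name to the WBcel235 gene annotation (18484 of 19652), which gave strand, symbol and coordinates. For 436 features without an annotated strand, the strand was set by the first base of their reads, a rule that was right for 99.7% of 4448 features with a known strand, and 732 had none. Repeat lines were left out. 22G reads were antisense, 21 to 23 nt long and began with G on their own strand. 26G reads were antisense, 26 nt long and began with G.

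Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, Benjamini-Hochberg) in R 4.3.3, with N2 and GFP::RDE-8 against rde-8 and GFP::RDE-8(D76N). The strains of a class stood as its replicates, so a p-value measures the spread between strains. Genes needed at least 10 reads in 2 libraries for 22G and 5 reads in 2 libraries for 26G. The coefficient of biological variation was 0.263 for 22G and 0.788 for 26G. Gene lists (ERGO-1 targets, sperm, oocyte and germline, WAGO class, small RNA pathway, yolk, histone and muscle genes) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation, with adjustment over 6 lists for 22G and 2 for 26G. Strain pairs were compared by size, with at least 50 reads and a 4-fold change, after 0.5 was added to each count.

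Named genes passed an adjusted p of 0.05 with the same sign in both strain pairs and an average level above the median of tested genes, and the 15 lowest and 15 highest log2 changes were taken. Members of fixed lists were named too. These rules, lists and tests were fixed before the data were examined. Log2 changes carry the standard error of the fit. A gene at 0 reads in both defective libraries was set against a floor of 3 reads per library.

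sel-1 siRNA measures were the log2 ratio of antisense to sense reads, the share of antisense reads of 22 nt with a 5′ G, and the share of those outside the trigger, taken as the central 98% of sense reads. They were compared between GFP::RDE-8 and D76N at 6 times with an exact two-sided sign-flip permutation test, in which 2000 null draws gave 2.90% calls. With 1 library per strain and time, its p-value measures the spread over times, not between worms. The first set (1, 3 and 7 h) and the second set (4, 8 and 24 h) are a grouping that the sample titles do not name. 3′ RACE measures were compared over 3 times in the same way. Position matches used circular shifts of the profile in 20-nt bins.

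The gene tests and the sign-flip test were tested on simulated data. With the fitted spread and 3729 genes, the 22G test recovered 56.2% of 4-fold and 82.6% of 8-fold losses and 88.0% and 100% of gains, and 8.62% of its calls were false. With 53 genes the 26G test recovered 0%. Alternatives were DESeq2 1.42.0, other scalings and filters, sequences of 1 position, other lengths, strain pair as a block, and each library or time left out. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

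miRNA and 21U tests and lists were left out, since the files list no such reads. A full count of each read at every position was left out, since the values are already divided and rounded. Reads per 1000000 for sel-1 were left out, since no depth is given.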

Results

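The series profiled small RNAs and mRNA 3′ ends of Caenorhabditis elegans gravid adults, per the labels, to ask what the ribonuclease RDE-8 does in endogenous and fed RNA interference (RNAi). It held 33 libraries in 33 groups, with 1 library per group, so no group had a replicate. 8 libraries came from unfed worms: wild type (N2), the rde-8(ne3361) mutant, and transgenic strains carrying GFP::RDE-8 or GFP::RDE-8(D76N), called D76N below, each made from phosphatase and polynucleotide kinase treated RNA (CIPPNK) and from untreated RNA (direct). Sample titles do not give the chromosomal rde-8 allele of the transgenic strains, so their class as intact or defective follows the transgene. CIPPNK treatment lets RNAs with a 5′ triphosphate enter a library, such as 22G RNAs, the antisense products of RNA-dependent RNA polymerases. Direct libraries take RNAs with a 5′ monophosphate, such as 26G RNAs, which start the ERGO-1 pathway. A further 14 CIPPNK libraries and 11 libraries of sel-1 mRNA 3′ ends (3′ RACE) came from worms fed bacteria that make sel-1 double-stranded RNA, or the empty vector L4440. Of the 3′ RACE libraries, 3 were of glp-4 strains, treated below as worms without a germline, so gravid cannot describe those.

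The unfed CIPPNK files listed 434710 reads for N2, 491112 for GFP::RDE-8, 341875 for rde-8 and 221476 for D76N, and the direct files 94998, 136284, 206384 and 252910 in that order. These totals count reads listed under coding transcripts, pseudogenes and transposons, not the depth of the libraries, which the files do not give. The sel-1 siRNA files held from 803 to 33026 reads, and the 3′ RACE files from 949102 to 8814659. Intervals below are 95% Wilson intervals, and they and the floors cover counting error only. The rde-8 gene (ZC477.5, chromosome IV, 7101379 to 7103261 in WBcel235) had between 5 and 8 22G reads in each unfed CIPPNK library, which checks nothing about its mutation.

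The first question was which endogenous 22G RNAs need RDE-8. 22G RNAs made up 61.4% of listed reads in N2 (61.2 to 61.5) and 61.8% in GFP::RDE-8 (61.7 to 61.9), against 45.4% in rde-8 (45.2 to 45.5) and 50.6% in D76N (50.3 to 50.8). Transposon 22G RNAs took 6.80% of listed reads in N2 and 5.69% in GFP::RDE-8, against 2.30% in rde-8 and 2.84% in D76N. Pseudogene 22G RNAs took 5.67% in N2 and 4.79% in GFP::RDE-8, against 3.25% in rde-8 and 3.77% in D76N. Sense reads, which hold fragments of the mRNAs themselves, moved the other way, from 12.19% in N2 and 14.8% in GFP::RDE-8 to 23.8% in rde-8 and 22.9% in D76N. With 2 strains against 2, an exact permutation test of a share cannot go below p = 0.333, so these shares stand as values.

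Among 4148 genes tested for a difference between the strains with intact RDE-8 (N2, GFP::RDE-8) and those without (rde-8, D76N), 676 had fewer 22G reads and 186 had more at an adjusted p under 0.05 by edgeR's quasi-likelihood test. The losses held 497 of 3626 coding genes, 56 of 148 pseudogenes and 123 of 374 transposons, and the gains 174, 12 and 0 in the same order. Of the transposons, edgeR had 144 lower and 0 higher at an unadjusted p under 0.05, DESeq2 called 33 and 0, and transposon copies share many reads. The strongest losses above the median 22G level included K07A1.3 (chromosome I, 9587148 to 9588153), which had 85 and 112 reads in N2 and GFP::RDE-8 and 0 in both other libraries. Set against a floor of 3 reads per library, K07A1.3 was at least 15.6-fold lower and F16F9.4, with 93 reads in the intact strains and 0 in the others, at least 7.24-fold lower. acs-5, which encodes an acyl-CoA synthetase, fell from 279 to 2 reads (67.8-fold, exact 95% counting interval 18.6 to 563), and klf-1, a Krüppel-like transcription factor gene, from 253 to 2 (61.5-fold, interval 16.9 to 511).

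Y38F2AR.12 fell by 5.50 ± 0.62 on the log2 scale (SE, 2 strains per class) and ckk-1, a calmodulin kinase kinase gene, fell by 4.94 ± 0.61. The other named losses were T20F7.1, prx-11 (peroxisome assembly), F36A2.3, the pseudogene Y17D7B.7, Y73B3A.7, gfi-3, eri-12, rimb-1 and C09E7.5, each with 1 to 3 reads in both defective libraries together. The largest gain was T20F7.5 (chromosome X, 16845374 to 16862005), with 4 and 15 reads in N2 and GFP::RDE-8 against 437 and 238 in rde-8 and D76N, a log2 change of 6.17 ± 0.57. ace-1, an acetylcholinesterase gene, rose by 4.54 ± 0.51 on the log2 scale, irld-23 by 3.74 ± 0.50 and gpa-1, a G protein alpha subunit gene, by 3.47 ± 0.49. The other named gains were F13D12.10, his-61, Y73B6A.1, F23A7.4, Y57G11C.5, C06E4.5, the riboflavin transporter gene rft-2, F44G4.3, lgc-33, Y25C1A.13 and chaf-2. Reads that chaf-2 shares with other positions carried its call, since with sequences of 1 position its log2 change was 0.88 (adjusted p = 0.341, edgeR), and F23A7.4 could not be tested that way. That of gpa-1 was 1.75 with such sequences (adjusted p = 0.0182).

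The loss was found in both mutant strains. By size alone (at least 50 reads and 4-fold), 238 genes were lower and 39 higher in rde-8 against N2, and 178 were lower and 19 higher in D76N against GFP::RDE-8. These pairs share no library, and 115 genes were lower and 11 higher in both, where 24.9 and 0.379 would be shared by chance among the 1224 genes with at least 50 reads in each pair, with 0 in opposite directions. Between the intact strains, 24 genes were lower and 5 higher in GFP::RDE-8 than in N2. Scaling by listed reads in place of TMM moved the median of all genes by -0.312 on the log2 scale and gave 845 lower and 76 higher genes, so the balance of losses and gains rests on the scaling. The counts also rested on single libraries: 23 genes were lower and 8 higher without N2, 251 and 56 without GFP::RDE-8, and 122 were higher without rde-8.

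Targets of the ERGO-1 pathway, which silences gene duplicates and other non-conserved genes, formed the group with the clearest loss among the lists fixed in advance. Of 31 tested members, 24 had fewer 22G reads and 0 more by edgeR (27 and 0 at an unadjusted p under 0.05, 14 and 0 by DESeq2), and 27 were lower adjusted over the list alone. K02E2.6 dropped from 672 and 752 reads in N2 and GFP::RDE-8 to 5 and 67 in rde-8 and D76N, C44B11.6 from 630 and 598 to 3 and 26, and Y37E11B.2 from 300 and 327 to 5 and 13. The list's median log2 change was -2.58. Its median was -3.64 in the rde-8 pair with members at 0 reads set to their floor (-4.79 with 0.5 added to each count). It was -1.60 in the D76N pair. In the D76N pair, C36A4.11 and K06B9.6 had log2 changes of 0.18 and 0.14, against -5.69 and -5.12 in the rde-8 pair. The adjusted p by camera with a preset correlation was 6.69e-17, and the adjusted p was 0.169 with an estimated correlation. Without N2, 21 members could be tested and 1 was lower, while the median stayed at -2.42.

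Most tested genes that carried 26G RNAs also had fewer 22G RNAs without intact RDE-8. The 60 genes with at least 20 26G reads over the direct libraries had 30260 22G reads per 1000000 listed reads in N2 and 21150 in GFP::RDE-8, against 1565 in rde-8 and 5679 in D76N. This was 19.3-fold lower in rde-8 than in N2 and 3.72-fold lower in D76N than in GFP::RDE-8, and 1.43-fold lower in GFP::RDE-8 than in N2. Of 49 such genes tested, 39 were lower and 0 higher by edgeR (43 and 0 at an unadjusted p under 0.05, 20 and 0 by DESeq2), and 43 were lower adjusted over the list alone. The set was drawn from libraries of the same strains, and 21 of its genes are also on the ERGO-1 list. Of the 29 tested genes outside that list, 22 were lower and 0 higher by edgeR, with 24 and 0 at an unadjusted p under 0.05. The adjusted p by camera was 6.9e-23, and the adjusted p was 0.169 with an estimated correlation. Without N2, 4 of 32 were lower, while the median was -2.20, against -2.68 with all libraries.

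**Figure D1:**
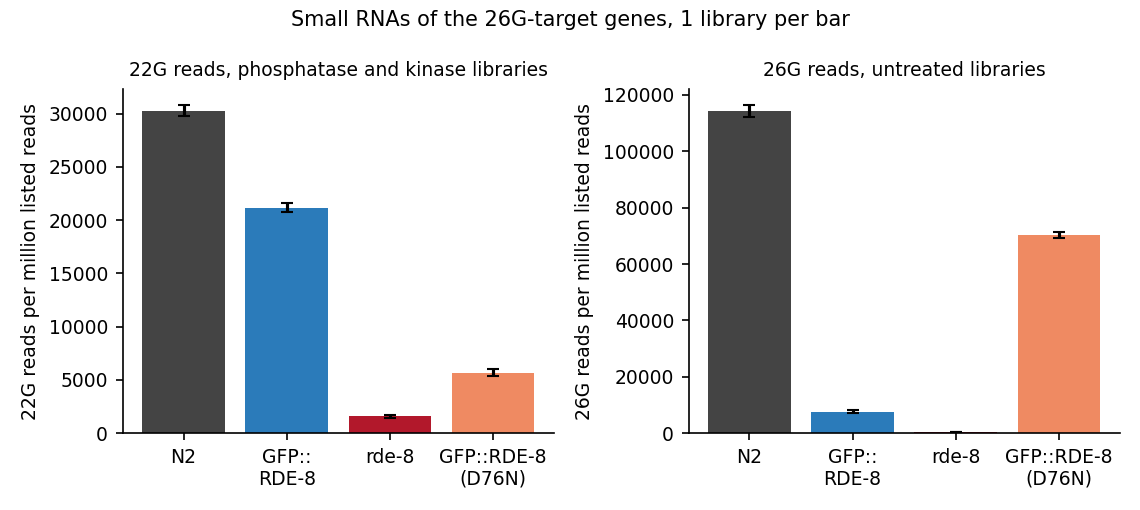
Bars show 22G reads in the CIPPNK libraries (left) and 26G reads in the direct libraries (right) of the 60 genes that carry 26G RNAs, per 1000000 listed reads, 1 library per strain, with 95% Wilson intervals. The 22G bars stand at 30260 and 21150 with intact RDE-8 and at 1565 and 5679 without it, while the 26G bars of GFP::RDE-8 and rde-8 are both low.

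Germline genes of the CSR-1 class, named for an Argonaute that binds 22G RNAs of expressed genes, held no member with a called loss. Of 27 tested, 0 were lower and 2 higher by edgeR (0 and 4 at an unadjusted p under 0.05), cey-2 at 1.49 ± 0.46 and him-3 at 1.35 ± 0.46 on the log2 scale, 0 passed adjusted over the list alone, and DESeq2 called 0 in either direction. Their median log2 change was 0.62, or 0.31 when scaled by listed reads (camera adjusted p = 0.000492, and adjusted p = 0.169 with an estimated correlation). Small RNA pathway genes had a median of 0.41, with 0 of 25 lower and 1 higher by edgeR (0 and 3 at an unadjusted p under 0.05, 0 and 1 by DESeq2). The higher gene was rde-4, which encodes a double-stranded RNA binding protein, at 1.67 ± 0.46, and it passed also adjusted over the list alone, but was not called with sequences of 1 position, without N2 or without GFP::RDE-8. The list had a camera adjusted p = 0.0195, and an adjusted p = 0.303 with an estimated correlation. Their camera p was 0.488 without N2, 0.123 without GFP::RDE-8 and 0.0985 with no filter on low counts.

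The WAGO class list split. xol-1, the switch gene of sex determination, fell by 4.10 ± 0.60 on the log2 scale, and C38D9.2, F15D4.5 and R03D7.2 fell by 2.70, 1.90 and 2.04, while R06C1.4 (-0.47), bath-45 (0.02) and bath-13 (0.03) did not pass. This made 4 of 7 lower and 0 higher by edgeR (4 and 0 at an unadjusted p under 0.05, 3 and 0 by DESeq2), with 4 lower adjusted over the list alone and a median of -1.90 (camera adjusted p = 0.0185, and adjusted p = 0.169 with an estimated correlation). C38D9.2 and F15D4.5 also differed between the intact strains, with 482 and 1570 reads in N2 against 134 and 362 in GFP::RDE-8. Without N2, only 5 of the 7 members could be tested, with a median of -0.50, so this median covers fewer members than the -1.90.

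Of 72 histone genes only 9 had enough 22G reads to test, and 5 of these had at least 10 reads only in the defective libraries, so the filter could favour gains. Of the 9, 8 were higher and 0 lower by edgeR (9 and 0 at an unadjusted p under 0.05, 4 and 0 by DESeq2), and 9 were higher adjusted over the list alone, with a median log2 change of 2.31 (camera adjusted p = 5.72e-11, and adjusted p = 0.169 with an estimated correlation). his-61 went from 3 and 0 reads in N2 and GFP::RDE-8 to 51 and 17 in rde-8 and D76N, and his-37 rose by 2.05 ± 0.51 on the log2 scale. Histone copies share reads: his-10, his-14 and his-26 carried identical counts, and with sequences of 1 position 3 of 5 members were higher. With no filter on low counts 19 of 71 were higher. Counts were low, and 1 of 9 members was higher without N2 (median 3.38), 6 of 9 without GFP::RDE-8 (2.92), 1 of 4 without rde-8 (1.19) and 2 of 4 without D76N (1.61). Of the sperm list, spe-41, a sperm calcium channel gene, fell by 3.41 ± 0.61 and fer-1 stood at 0.21 ± 0.68, and 0 of the yolk and 0 of the muscle genes had enough reads to test.

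**Figure D2:**
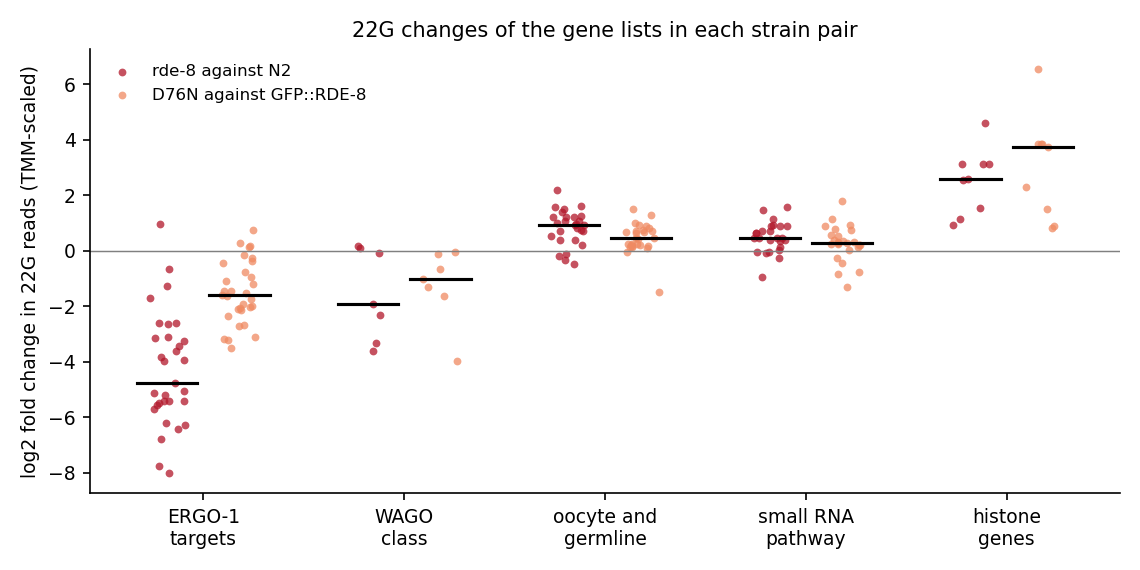
Points show the log2 change in TMM-scaled 22G reads of each tested member of 5 gene lists, in rde-8 against N2 (red) and in D76N against GFP::RDE-8 (orange), with black lines at the medians. Members at 0 reads are drawn at values set by 0.5 added to each count, which are no bounds. The ERGO-1 medians are -4.79 and -1.60, the histone medians 2.59 and 3.72.

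The direct libraries addressed whether 26G RNAs, upstream of these 22G RNAs, also need RDE-8. They made up 11.61% of listed reads in N2 (11.4 to 11.8) and 0.084% in rde-8 (0.073 to 0.098), a 138-fold lower share. The transgenic strains went the other way: 26G RNAs made up 7.14% of listed reads in D76N (7.04 to 7.24) and 0.836% in GFP::RDE-8 (0.789 to 0.886), 8.54-fold more in D76N. On the ERGO-1 list, N2 had 45140 26G reads per 1000000 listed reads, D76N 28350, GFP::RDE-8 2992 and rde-8 48.4 (10 reads). In the CIPPNK libraries, where few 26G RNAs are captured, the same list had 158 per 1000000 listed reads in N2 (68 reads), 151 in GFP::RDE-8 (74 reads), 126 in D76N (28 reads) and 0 in rde-8, which allows up to 8.78.

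Of 61 genes tested for 26G RNAs, 0 were lower and 0 higher by edgeR, with 0 and 0 at an unadjusted p under 0.05, and DESeq2 called 0 and 0, with 0 and 2 at an unadjusted p under 0.05. By size per 1000000 listed reads, an alternative chosen after the values were seen, 33 of 33 genes with enough reads were lower in rde-8 than in N2. 31 of 36 were higher and 0 lower in D76N than in GFP::RDE-8, and 27 genes went in opposite directions in the pairs. The read minimum shaped these counts. No tested gene had over 36 reads of 26G RNAs in rde-8 (Y61B8A.6, with 9 in N2), so genes passed through their N2 reads. Being lower in rde-8 was thus all but fixed by the filter, and 33 of 33 is no separate evidence. The D76N library held 18049 26G reads against 1139 in GFP::RDE-8, so the minimum favoured genes higher in D76N. TMM scaling removes a change that all 26G genes share, and with it 6 genes were lower in the rde-8 pair. On the ERGO-1 list 0 of 22 tested members passed in either direction over all genes or adjusted over the list alone (0 by DESeq2; camera adjusted p = 0.142, and adjusted p = 0.387 with an estimated correlation). Simulated data with the fitted spread gave 0% recovery of 4-fold and 8-fold changes among 53 genes.

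Feeding sel-1 double-stranded RNA (sel-1, F45D3.5, chromosome V, 12560732 to 12563383) asked how fast 22G siRNAs appear on an RNAi target. In GFP::RDE-8 worms, 22-nt reads with a 5′ G made up 2.42% of antisense sel-1 reads at 1 h (2.14 to 2.73), 12.15% at 3 h (11.47 to 12.87) and 22.1% at 7 h (21.6 to 22.7). In D76N worms the share was 6.06% at 1 h (5.46 to 6.72), 2.72% at 3 h (2.43 to 3.05) and 4.81% at 7 h (4.36 to 5.31). In the second set, it was 5.53%, 37.4% and 44.1% at 4, 8 and 24 h in GFP::RDE-8, and 3.49%, 3.32% and 30.6% in D76N. The L4440 libraries, with 306 and 327 antisense reads, had 19.6% (15.6 to 24.4) and 23.9% (19.6 to 28.8), so background reads are themselves partly 22G and the share is not a level. Over 6 matched times the GFP::RDE-8 share was higher by 12.1 ± 13.2 percentage points (SD, 5 of 6 times; exact two-sided sign-flip permutation p = 0.0938, adjusted p = 0.234 over 3 measures), where the smallest possible p is 0.0313. This SD and p-value measure the spread over times of 1 strain pair, not between worms. Counted as distinct sequences the difference was 1.58 points (4 of 6 times), and it was 7.74 without 8 h and 7.70 in the first set alone.

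**Figure D3:**
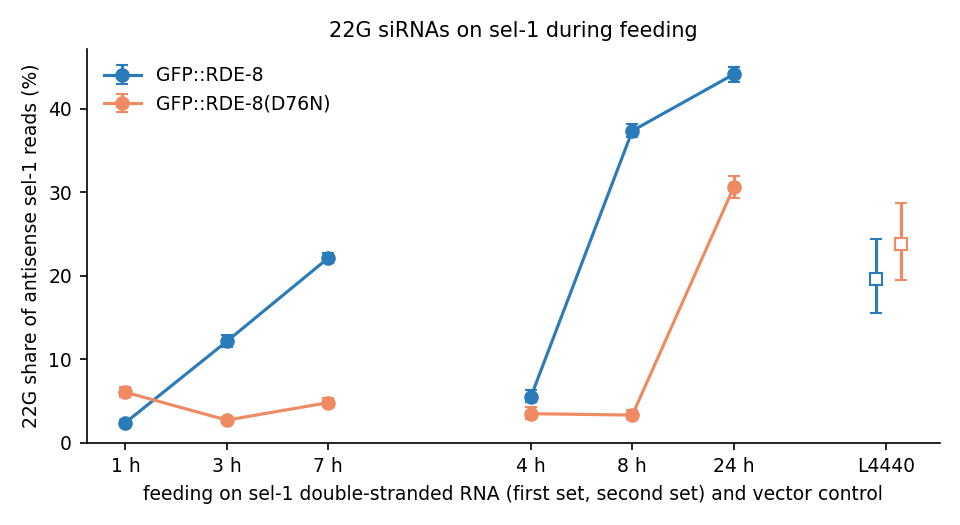
Points show the share of antisense sel-1 reads that are 22 nt long with a 5′ G, with 95% Wilson intervals, against hours of feeding in the first and the second set, and in the L4440 controls (open squares). The GFP::RDE-8 share is 22.1% at 7 h and 37.4% at 8 h, against 4.81% and 3.32% in D76N.

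The balance of antisense and sense sel-1 reads went both ways. At 24 h there were 10.36 antisense reads per sense read in GFP::RDE-8 and 1.42 in D76N, and at 7 h 1.84 and 0.982, but at 8 h 0.878 and 0.996, at 4 h 0.603 and 0.746, and on L4440 0.05 and 0.687. The log2 ratio differed by 0.70 ± 1.16 over the 6 times (4 of 6 above 0; exact permutation p = 0.156, adjusted p = 0.234), by 0.27 without 24 h and by 0.30 as distinct sequences. Many sense reads began within 1 nt of the 4 start sites of the 3′ RACE reads: 93.8% of sense reads in the GFP::RDE-8 L4440 library, 56.5% in the D76N one, and from 2.17% to 84.0% in fed libraries. These reads enter the ratio and the region taken as the trigger, and without them, an alternative chosen after they were seen, the log2 ratio differed by 0.78 (4 of 6 above 0). The 8 h ratios then turned to 5.48 in GFP::RDE-8 and 1.35 in D76N, and those on L4440 were 0.799 and 1.58.

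Some 22G siRNAs lay outside the region of sense reads, taken as the trigger. The central 98% of sense reads spanned positions 438 to 1572 of the 2053-nt sel-1 cDNA, or 478 to 1587 without the RACE start sites. With the latter, 24.4% of 22G reads at 7 h lay upstream in GFP::RDE-8 and 5.0% in D76N (19 reads), and at 24 h 17.8% and 14.1%. On L4440 the upstream share was 16.7% (10 reads) and 15.4% (12 reads). Downstream of it lay 0.669% and 1.32% at 7 h. With the region fixed in advance, the share outside it was higher in GFP::RDE-8 by 4.76 ± 8.38 points (3 of 6 times; exact permutation p = 0.344, adjusted p = 0.344), and by 2.17 without 3 h. It was 10.9 points higher in the first set (3 of 3 times) and lower in the second (-1.37, 0 of 3 above 0). Without the RACE start sites it was 10.3 points higher (5 of 6 times; exact permutation p = 0.0625, adjusted p = 0.141), 17.6 in the first set and 3.1 in the second.

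**Figure D4:**
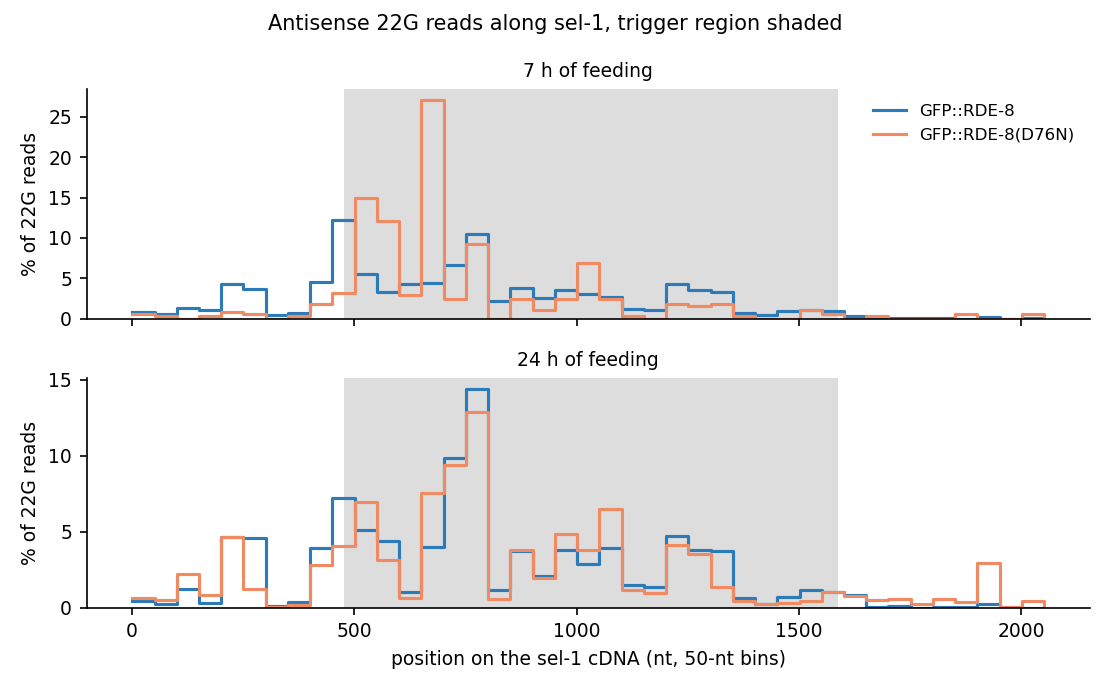
Lines show the percentage of antisense 22G reads of sel-1 in 50-nt bins along its cDNA, at 7 h and 24 h of feeding, in GFP::RDE-8 (blue) and D76N (orange), with positions 478 to 1587 shaded. Upstream of the shaded region lie 24.4% and 5.0% of reads at 7 h, and 17.8% and 14.1% at 24 h.

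The 3′ RACE libraries asked where sel-1 mRNA is cut and whether its ends carry added uridines. Their files list reads only where part of the read does not match sel-1, so the share of ends with a tail could not be measured. Unmatched ends made only of U were 9.12% of listed reads in GFP::RDE-8 at 7 h (9.07 to 9.18), 1.67% at 3 h (1.66 to 1.68) and 0.233% at 1 h (0.230 to 0.237). In D76N they were 0.319% at 7 h (0.313 to 0.325), 0.135% at 3 h (0.132 to 0.137) and 0.277% at 1 h (0.274 to 0.281). The background was 2.15% in GFP::RDE-8 on L4440 (2.13 to 2.17) and 1.59% in D76N on L4440 (1.57 to 1.60), and the GFP::RDE-8 library at 7 h was the only one above the background of its strain. Of unmatched ends made of only 1 kind of base, at any length, 67.3% were U at 7 h in GFP::RDE-8 and 37.8% in D76N. At 1 h the U shares were 6.26% and 18.6%, and over 3 times the difference was 18.3 ± 26.8 points (SD, 2 of 3 times; exact permutation p = 0.5, adjusted p = 0.75). On L4440 they were 33.3% and 21.5%, and counted as distinct sequences the difference was 0.762 points.

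Over 3 matched times the U-only share was higher in GFP::RDE-8 by 3.43 ± 4.72 points (SD, 2 of 3 times; exact permutation p = 0.5, adjusted p = 1, smallest possible p 0.25), and by 0.75 without 7 h, 4.38 without 3 h and 5.17 without 1 h. Counted as distinct sequences the difference was 0.08 points. U-only ends of the GFP::RDE-8 7 h library lay at 51 positions, 34.3% of them at position 456, and in both L4440 libraries position 482 held 51.7% and 55.6%. In worms without a germline (glp-4, 48 h of feeding), U-only ends made up 56.7% of reads in GFP::RDE-8 (56.6 to 56.7) and 50.6% in D76N (50.5 to 50.7), and U-only ends of at least 2 nt 27.4% and 13.1%. With that pair the difference was 4.09 points (exact permutation p = 0.25, adjusted p = 1).

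**Figure D5:**
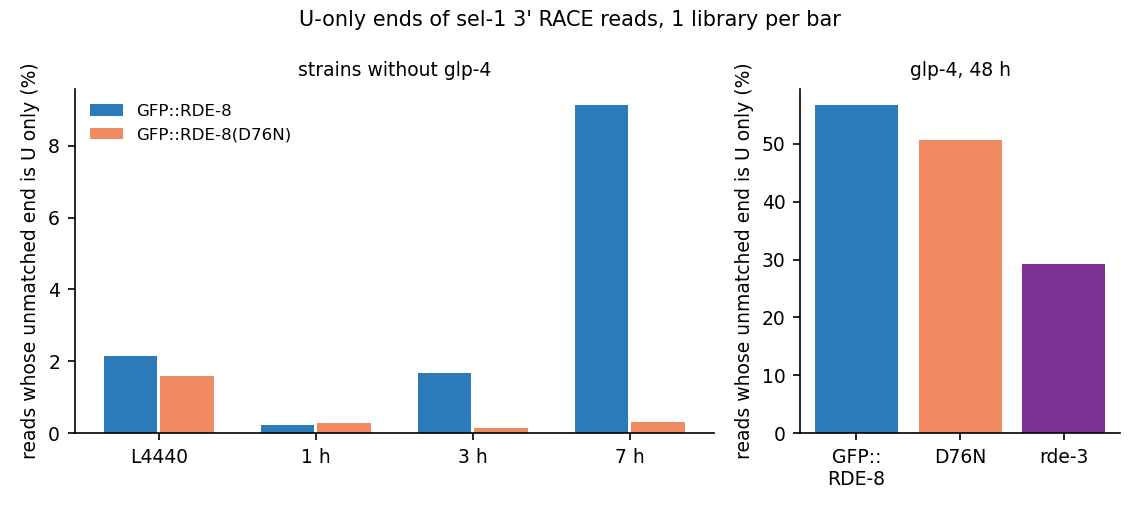
Bars show the percentage of listed sel-1 3′ RACE reads whose unmatched end is only U, 1 library per bar, in strains without glp-4 by hours of feeding (left) and in glp-4 strains at 48 h (right, on another scale). The GFP::RDE-8 bar reaches 9.12% at 7 h and the D76N bar 0.319%.

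With 3 pairs no RACE measure could pass a test, so the others stand as values too. The median 3′ end was position 476 in each fed time course library, where a junction that reads into other sequence held from 17.7% to 64.0% of reads. The mean unmatched part was longer in GFP::RDE-8 by 0.39 ± 1.07 nt (2 of 3 times; exact permutation p = 0.75, adjusted p = 1). In the time course libraries all 3′ ends lay within positions 438 to 1572, so that measure was saturated there. Within 478 to 1587, drawn without the RACE start sites after the values were seen, their share was higher in GFP::RDE-8 by 11.3 points (3 of 3 times; exact permutation p = 0.25, adjusted p = 1), but on L4440 it was 25.8% against 15.8% in D76N, so the gap was there without sel-1 feeding. U-only ends of at least 2 nt, a measure added later, were higher by 0.605 points (3 of 3 times; exact permutation p = 0.25, adjusted p = 0.75), by 0.05 as distinct sequences, and on L4440 they already stood at 0.823% and 0.1995%. RACE reads covered only a small window of sel-1, so their match with siRNA positions over the whole cDNA says mainly where reads were. Across 20-nt bins, which are not independent replicates, Spearman's rho between 3′ ends and 22G positions lay between 0.093 and 0.284 (circular-shift permutation, lowest adjusted p = 0.224 over 6 libraries).

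miRNAs and 21U RNAs were not analysed here, since the files list neither class.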

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

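The swap test and the carry-over test were chosen only after the result was seen.

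26G RNAs of the direct libraries were flagged because the strain pairs moved in opposite directions: the 26G share changed by -11.5 points in rde-8 against N2 and by 6.30 points in D76N against GFP::RDE-8, with 1 library each, and the difference was not tested. A swap of the transgenic direct libraries is argued against, since D76N to GFP::RDE-8 ratios of 22G reads in direct and CIPPNK libraries correlated positively across 332 genes (Pearson r = 0.384, against 0.666 for rde-8 to N2), and across the 307 outside the 26G-target set and the ERGO-1 list (0.499 against 0.544), genes not being independent replicates, although on the ERGO-1 list 22G reads per 1000000 went the other way (692 in D76N and 439 in GFP::RDE-8, against 3614 and 12150 in CIPPNK). A loss of RNAs of about 26 nt from the GFP::RDE-8 direct library is argued against too, since sense reads of 25 to 27 nt made up 0.964 times the share they had in N2. What stays open and untested is a strain difference, and a difference in worm stage between the 1-library groups. The rde-8 strain, with 0 26G reads on the ERGO-1 list in its CIPPNK library as well, is labelled by an rde-8 allele, and D76N by its transgene. The sample titles do not give the chromosomal rde-8 allele of the transgenic strains. In the CIPPNK libraries 26G reads of the 60 target genes were 432 per 1000000 listed reads in N2, 270 in GFP::RDE-8, 252 in D76N and 92.9 in rde-8, so GFP::RDE-8 was 1.60-fold below N2 there and 14.97-fold below it in the direct libraries.

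In the same libraries the sense share moved by 17.3 points in rde-8 against N2 and by -5.13 in D76N against GFP::RDE-8. The antisense share is its complement and moved by -17.3 and 5.13, opposite in the pairs and not tested. It includes the 26G reads, whose share changed by -11.5 and 6.30 points, so this is no separate result. The share of other antisense reads fell in both pairs.

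Sense sel-1 reads at the 3′ RACE start sites in the siRNA libraries were weighed because they were abundant without sel-1 feeding. Dicer products of the fed RNA are argued against, since 14.7% of these reads were 21 to 23 nt long against 23.2% of other sense reads. Carry-over of RACE products cannot be told apart from other sources: even the lower L4440 library had 56.5% of its sense reads there, against a median of 25.5% in fed libraries, but such a share rises where no fed RNA adds sense reads, and the library depth is not in the files. No other biological explanation was tested, and a source shared by both kinds of library stays open.

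The share of sel-1 22G reads outside the trigger was flagged because the sets moved apart: it was higher in GFP::RDE-8 by 10.9 points in the first set (3 of 3 times) and changed by -1.37 in the second (0 of 3 above 0), a difference that was not tested. With the trigger drawn without sense reads at the RACE start sites, chosen after the values were seen, both sets were higher, by 17.6 points (3 of 3 times) and 3.1 points (2 of 3), so the opposite direction ended.

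The rde-3;glp-4 3′ RACE library, which no comparison used, was flagged because 29.3% of its listed reads had U-only ends (29.3 to 29.4). That was above both L4440 libraries, which were of strains without glp-4. It was below the other glp-4 libraries, GFP::RDE-8;glp-4 at 56.7% and GFP::RDE-8(D76N);glp-4 at 50.6%. Shares of glp-4 and L4440 libraries are not on the same basis. Only the glp-4 titles name a temperature and a sel-1 mix. Their reads began at sites 409, 429, 448 and 465, in place of 437, 447, 457 and 465. The junction found mainly at position 476 held 0.063% of rde-3;glp-4 reads, against 20.7% and 40.3% on L4440.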

How the results depend on the processing

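Tests without RACE start sites, by listed reads per pair, of lists under each setting and of chromosomes were chosen after the data were seen. Of 44 alternative counts of 22G and 26G genes, 33 stayed within 1.5 times the main count. The 26G counts among them could hardly move, since that test recovered 0% of simulated changes at the fitted spread. The 33 therefore say little about the 22G counts. Against 676 lower and 186 higher 22G genes, DESeq2 called 282 and 51 (617 and 168 at an unadjusted p under 0.05) and sequences of 1 position 416 and 59, with 3449 genes tested. Listed reads left 76 higher, and all 676 lower genes were among its 845. Leaving out 1 library gave from 23 lower (without N2) to 538 (without D76N) and from 8 higher to 189. Without N2 or GFP::RDE-8, fewer genes could be tested (2873 and 2710), since a gene with reads in the intact strains alone then fails the filter. All 15 named losses failed it in both cases, so only named gains were tested there. The 26G counts stayed at 0, except 1 higher with no filter. Named genes were picked for the same sign in both strain pairs of these libraries, which all but fixed their sign below. Named genes kept their sign in all 291 comparisons and fell short of the threshold in 12, 10 of them without N2, where 15 of 30 could be tested.

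With an estimated correlation the adjusted p of the ERGO-1, CSR-1, WAGO, histone and 26G-target lists rose to 0.169 and that of the small RNA list to 0.303, and the cause was not tested. In 22G data the 26G-target set kept its direction when drawn with a lower or a higher minimum of 26G reads. The 22G list medians kept their sign in 66 comparisons, with 4 short of the threshold. In 26G data 5 of 22 comparisons passed it. The median of 26G targets reversed there without N2, and went from -4.43 (without D76N) to 0.117 leaving out 1 library. In each of these, 34 genes were tested in place of 60. The 26G-target list was drawn from these same 26G reads and holds 60 of the 61 genes tested. Its camera p in 26G data therefore sets it against almost no other genes and says nothing. By listed reads, 12 in place of 19 genes were higher in D76N against GFP::RDE-8.

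Of 63 alternatives for sel-1 siRNA, 1 reversed, the outside share in the second set alone (-1.37), which stood at 3.1 with the trigger drawn without the RACE start sites, and no other cause was tested. Some of the 63 could not differ from the main result. The trigger bounds do not enter the ratio or the 22G share, and sense reads at the start sites do not enter that share. Of 45 for 3′ RACE, 3 reversed, all for the unmatched length: -0.678 nt with distinct sequences, -0.008 with longer matched parts, and from -0.145 (without 7 h) to 0.927 (without 1 h) leaving out 1 time, and the cause was not tested. With 3 pairs no p could pass, so these say nothing about stability. Position matches kept their side of the threshold in 18 comparisons. The miRNA and 21U alternatives and full counts at every position were not run. In simulated data 56.2% of 4-fold 22G losses were recovered, so others of that size would be missed, and the sel-1 L4440 libraries held only 803 and 6464 reads.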

Other observations

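The chromosome tests were chosen only after the 22G test was seen, and their predictions on X were written before its matched lists and pair values.

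Genes on the X chromosome lost more 22G reads than autosomal genes. Of 245 tested X genes, 105 were lower and 8 higher without intact RDE-8 (42.9% lower), against 10.7% to 16.9% lower on the autosomes. The median log2 change of X genes was -1.27, against 0.15 for 3485 autosomal genes, and it was -1.31 in the rde-8 pair, -1.08 in the D76N pair and -0.04 in GFP::RDE-8 against N2. As a set, X had a camera adjusted p of 4.01e-11, and an adjusted p of 0.0684 with an estimated correlation. Named X genes went both ways: F16F9.4, T20F7.1, Y73B3A.7 and gfi-3 fell, and T20F7.5, ace-1, irld-23 and F23A7.4 rose.

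The 22G level of X genes is argued against as the whole cause, since 0 of 10000 random lists of autosomal genes matched on level had a median as low. Reads shared with copies are argued against, since the difference of medians was -1.42 with all reads and -1.52 with sequences of 1 position. A single strain pair is argued against, since the difference was -1.52 in the rde-8 pair and -1.14 in the D76N pair. A hypothesis that remains is that 22G RNAs on X may depend more often on RDE-8, found and tested on the same data. Some members of the ERGO-1 list, whose median log2 change was -2.58, lie on X. Members of the gene lists were not removed from X, and the random lists were matched on level alone. Whether a different mix of these gene classes on X and the autosomes accounts for the loss was therefore not tested. A difference in worm stage or germline content between strains stays open as untested too.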
